A study of Homo sapiens with 14 samples.

How the data were processed

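The data were gene-level RNA sequencing counts of 14 Jurkat libraries. Per the labels, polyadenylated RNA was sequenced from cells given DMSO or the KSR inhibitor APS-2-79 and from cells carrying a non-targeting guide or 1 of 2 *KSR2* guides. The labels disagree on the genetic method, since titles speak of CRISPR knockout, the design text of CRISPR interference and the library names of the control of a hairpin, so the groups are called guide 1, guide 2 and NT here. Dose, treatment time, guide sequences and the length of culture with the guides are not given in the sources used here. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

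The authors deposited a table of whole-number counts per Ensembl gene, not normalized. Per the submitters' processing notes, STAR 2.7.11b, DESeq2 1.42.1 and the GRCh38 build were used. The program that counted reads, its strand setting and the annotation release are not given in the sources used here. Such choices affect genes that overlap, lie antisense to each other or share reads with near-identical copies. The table held 61541 genes, of which 25747 had 0 counts in all libraries. Symbols were found for 61369 identifiers and not for 172. Positions are those of the GRCh38 gene annotation used here.

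Counts were analysed with edgeR 4.0.16 in R 4.3.3. TMM factors were computed, genes were kept by filterByExpr on the 5 groups (18963 genes, holding at least 99.93% of the counts of each library), and 1 mean per group was fitted over all 14 libraries, which share an estimate of the spread because NT has 2 libraries. The common biological coefficient of variation was 8.6%. Contrasts were tested with the quasi-likelihood F test, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. Comparisons were KSRi with DMSO, each guide and the mean of both with NT, guide 2 with guide 1, and the inhibitor effect with the guide effect. CPM values use the TMM-scaled library sizes, and errors are SDs between libraries or standard errors of log2 changes.

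Gene lists (34, of which 31 had at least 5 tested members) were tested with camera from limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, with adjustment over the lists of a contrast. Camera with an estimated correlation and fry were run beside it. Fry asks whether the genes of a list move, on balance, in 1 direction and does not compare them with other genes. The lists, the tests and the rule for naming genes were fixed before the data were examined. Named genes are *KSR2* and *KSR1*, the 7 called genes with the largest rise and the 7 with the largest fall with the inhibitor and with both guides (4 each between the guides), up to 5 per direction shared by the inhibitor and the guides, and up to 4 members with the lowest adjusted p from each list that was called or had at least 3 changed members. The largest changes were taken among genes of at least 5 CPM in the higher group, with a symbol and with no overlap between the libraries compared, and for both guides also with a call in each guide alone. In 3 fixed lists (the cascade, its outputs and the TAL1 circuit) up to 4 members with the lowest p are named whether called or not. Some genes that this rule names are not reported here.

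Alternatives were RLE and upper-quartile factors, no low-count filter, a filter of 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a fit of only the groups compared, a block for the replicate number, each library left out in turn, an adjusted p under 0.01 and a change of at least 2-fold. Replicate libraries differed by more than sampling noise (chi-square per degree of freedom 5.53 to 45.23), so all 14 were kept as separate. KSRi pairs ranged from 16.02 to 45.23, DMSO pairs from 5.53 to 7.48 and pairs of the other groups from 7.81 to 26.92. The shared estimate of the spread does not allow for this difference between groups.

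The procedure was tested on simulated data, counts drawn for the real genes. In these, 200 genes of at least 1 CPM were changed, and a further list of genes was shifted together. For KSRi against DMSO it recovered 74.6% of 1.5-fold, 91.0% of 2-fold and 100% of 4-fold changes, with 18 false calls. For both guides against NT it recovered 74.6%, 97.0% and 100%, with 16 false calls. The adjusted threshold is looser where many genes change. Recovery may therefore be lower in a contrast with few changed genes, and for scarcer genes it was not simulated. The 95% interval of the change with both guides had a median half-width of 0.25 on the log2 scale, and lay within −1 to 1 for 16580 genes (87.4%).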

Results

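Jurkat cells, a human line of TAL1-positive T-cell acute lymphoblastic leukaemia, were profiled by RNA sequencing of polyadenylated RNA under chemical or genetic interference with KSR2. KSR2 is a scaffold protein of the RAF, MEK and ERK kinase cascade, closely related to KSR1. The 14 libraries fell into 5 groups. Cells given the KSR inhibitor APS-2-79 (KSRi, n = 3) had solvent controls (DMSO, n = 3). Cells carrying KSR2 guide 1 (n = 3) or guide 2 (n = 3) had a non-targeting guide as control (NT, n = 2). Library totals were 27099107 to 43027877 counts for DMSO, 21710466 to 45897075 for KSRi, 25794010 to 34535929 for NT, 33919545 to 38801454 for guide 1 and 29979565 to 42717502 for guide 2. Libraries of one group had log2 CPM values correlated at 0.988 to 0.995 across genes. Between the control groups, DMSO and NT, this correlation was 0.956 to 0.959. The share of mitochondrially encoded transcripts was 1.36% ± 0.09 (SD, n = 3) for DMSO, 1.90% ± 0.71 (n = 3) for KSRi, 2.17% ± 0.46 (n = 2) for NT, 2.03% ± 0.31 (n = 3) for guide 1 and 1.79% ± 0.82 (n = 3) for guide 2.

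To see whether the guides acted on their target, *KSR2* itself was examined first. *KSR2* (ENSG00000171435; chromosome 12, 117453012 to 117968983, GRCh38) stood at 29.5 ± 0.786 CPM (SD, n = 2) with the non-targeting guide, at 0.541 ± 0.110 CPM (n = 3) with guide 1 and at 0.766 ± 0.0492 CPM (n = 3) with guide 2. Guide 1 lowered the transcript 53.9-fold (log2 change −5.75, SE 0.12, edgeR quasi-likelihood adjusted p = 6.89e-15). With guide 2 the fall was 38.5-fold (log2 change −5.27, SE 0.12, edgeR adjusted p = 1.48e-14). The guide libraries thus retained 1.83% and 2.60% of the NT level. The inhibitor left *KSR2* at 34.3 ± 1.20 CPM against 37.0 ± 2.23 CPM in DMSO (n = 3 each), a log2 change of −0.11 (SE 0.08) that did not pass the test (edgeR adjusted p = 0.276). *KSR1* (ENSG00000141068; chromosome 17, 27456470 to 27626438) rose 1.47-fold with the inhibitor, from 21.7 to 32.1 CPM (log2 change 0.56, SE 0.08, edgeR adjusted p = 6.15e-05). Across both guides its log2 change was −0.08 (SE 0.08, edgeR adjusted p = 0.989). In NT itself *KSR1* stood at 30.3 CPM, 1.40-fold above DMSO (edgeR adjusted p = 0.000202).

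**Figure D1:**
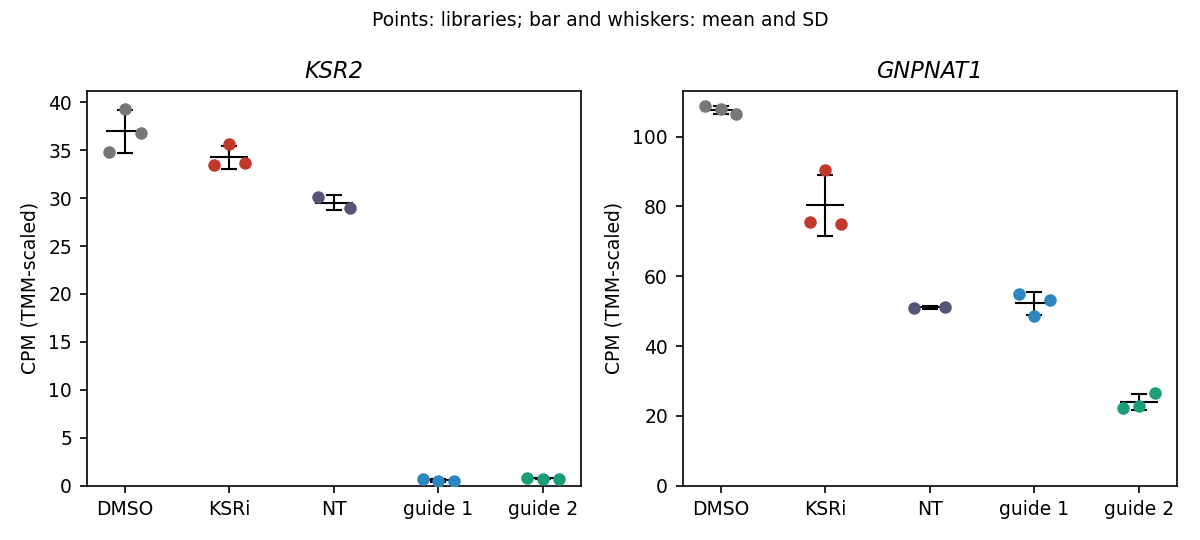
CPM of *KSR2* and *GNPNAT1* in each library of the 5 groups, with points for libraries and bars with whiskers for the group mean and SD. *KSR2* fell to 0.541 and 0.766 CPM in the groups of guides 1 and 2, while *GNPNAT1* stood at 52.3 CPM with guide 1 and 24 CPM with guide 2.

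The comparison of KSRi with DMSO asked which transcripts responded to the inhibitor. Genes of lipid synthesis rose, and the cholesterol list had the highest median change of the 31 lists tested. *ACSS2* (ENSG00000131069; chromosome 20, 34872146 to 34927962), which makes acetyl-CoA from acetate, went from 2.01 ± 0.366 to 80.9 ± 15.6 CPM (n = 3 each), a 40.3-fold rise (log2 change 5.33, SE 0.16, edgeR adjusted p = 6.97e-13). *HMGCS1* (ENSG00000112972; chromosome 5, 43289395 to 43313512), an early enzyme of cholesterol synthesis, went from 658 ± 8.92 to 6019 ± 311 CPM, a 9.15-fold rise (log2 change 3.19, SE 0.08, edgeR adjusted p = 3.76e-14). Of 22 tested genes of cholesterol synthesis and uptake 21 rose and 0 fell, with a median log2 change of 1.95. They included *MSMO1*, a sterol oxidase (7.10-fold), and *INSIG1*, a sterol sensor (6.76-fold). Of 12 tested genes of fatty acid synthesis 11 rose and 0 fell (median log2 change 1.23), among them the fatty acid synthase *FASN* (5.08-fold), the citrate lyase *ACLY* (4.24-fold) and the desaturase *SCD* (3.67-fold). Each list stood apart from other genes by limma camera (adjusted p = 3.79e-23 for cholesterol and 3.11e-09 for fatty acids). With an estimated correlation between genes these adjusted p values were 0.0204 and 0.0437.

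Genes of ribosome production, the heat shock response and mitosis were mostly lower with the inhibitor. Among 24 tested ribosome biogenesis and MYC target genes, 23 fell and 0 rose (median log2 change −0.73, camera adjusted p = 1.05e-13). *GNL3*, a nucleolar GTPase, fell 1.99-fold. On the log2 scale *UTP20* changed by −0.87 (SE 0.07), *DKC1* by −0.81 (SE 0.07) and *POLR1B*, a subunit of RNA polymerase I, by −0.79 (SE 0.06). Of 18 tested heat shock genes 13 fell and 1 rose (median −0.56, camera adjusted p = 3.17e-06), including *CHORDC1* (−1.26), *HSPH1* (−0.88), *HSPD1* (−0.78) and *HSPA4* (−0.59). Of 24 tested mitotic genes 17 fell and 0 rose (median −0.36, camera adjusted p = 4.25e-06), such as *KIF23* (−0.67) and the mitotic kinase *PLK1* (−0.64). With an estimated correlation the adjusted p was 0.00327 for ribosome biogenesis, 0.0128 for heat shock and 0.0961 for mitosis, so the call for mitosis was lost.

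ERK output and feedback genes were lower as a group, and immediate early genes were not. Of 15 tested ERK output and feedback genes 7 fell and 1 rose (median log2 change −0.34, camera adjusted p = 0.00338, and adjusted p = 0.0437 with an estimated correlation). The feedback inhibitors *SPRED1* (log2 change −0.84, SE 0.07), *SPRED2* (−0.74, SE 0.08), *SPRY4* (−2.15, SE 0.24) and *SPRY1* (−0.42, SE 0.10) all fell. *SPRY4* was scarce, at 1.48 CPM in DMSO and 0.339 CPM in KSRi. Of 19 tested immediate early genes 6 rose and 3 fell (median log2 change 0.07, camera adjusted p = 0.405, and adjusted p = 0.728 with an estimated correlation). Components of the RAF, MEK and ERK cascade moved both ways, with 4 of 20 higher and 5 lower (camera adjusted p = 0.549). *MAPK3*, which encodes ERK1, rose 1.80-fold, *ARAF* rose 1.45-fold and *MAP2K2*, which encodes MEK2, rose 1.25-fold. The TAL1 core regulatory circuit also moved both ways, with 2 of 16 genes higher and 3 lower (camera adjusted p = 0.549). *UBE2H* rose 1.67-fold, while *LMO1* fell 1.51-fold and *MYB* 1.34-fold. Of the NOTCH target genes 9 of 15 fell and 1 rose (median −0.40, camera adjusted p = 0.00164, but adjusted p = 0.14 with an estimated correlation). Among them *PTCRA*, the pre-T-cell receptor alpha chain, changed by −0.98, *SHQ1* by −0.80 and *DTX1* by −0.67, and *CR2* by 0.75.

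Stress, FOXO and immune genes made up the remaining groups that were higher with the inhibitor. Of 23 tested genes of the ATF4 amino acid response 20 rose and 0 fell (median log2 change 0.73, camera adjusted p = 2.08e-09, but adjusted p = 0.14 with an estimated correlation), with *CHAC1* up 6.96-fold, *PCK2* 3.76-fold, the cystine transporter *SLC7A11* 3.27-fold and *VLDLR* 2.82-fold. FOXO and PI3K-restrained genes rose in 13 cases and fell in 4 of 24 (median 0.33, camera adjusted p = 0.00149, but adjusted p = 0.14 with an estimated correlation), with *PIK3IP1* up 9.24-fold, *CCNG2* 3.24-fold, *ARRDC3* 3.15-fold and *SESN3* 3.08-fold. Of 21 tested p53 target genes 14 rose and 3 fell (median 0.34, camera adjusted p = 0.00338, but adjusted p = 0.14 with an estimated correlation), including *TP53INP1* (6.08-fold), *CDKN1A* (2.29-fold), *TP53I3* (2.26-fold) and *BTG2* (2.18-fold). Jurkat cells are known to lack functional p53. Of 13 tested MHC genes 12 rose and 0 fell (median 0.69, camera adjusted p = 0.000215, but adjusted p = 0.274 with an estimated correlation), with *HLA-B* up 1.79-fold, *HLA-C* 1.67-fold and *TAPBP* 1.43-fold. HLA genes resemble each other, so how shared reads were counted leaves the split among them uncertain. Of 26 tested interferon response genes 15 rose and 2 fell (median 0.47, camera adjusted p = 0.00847, and adjusted p = 0.0487 with an estimated correlation), including *IRF7* (2.57-fold), *MX2* (2.28-fold), *IFI6* (1.81-fold) and *STAT2* (1.62-fold). In each of the 12 lists called, and in the cascade and TAL1 lists, the number of changed members adjusted over the list alone equalled that adjusted over all genes.

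In all, 7712 of 18963 tested genes (40.7%) differed between KSRi and DMSO at an edgeR adjusted p under 0.05, with 4175 higher and 3537 lower. At least a 2-fold change was seen for 1475 of these, of which 1051 were higher and 424 lower. The largest rises beside *ACSS2* were taken among genes of at least 5 CPM in the higher group, with a symbol and no overlap between libraries. They were in *TTN* (38.7-fold), *PPM1K-DT* (17.3-fold), *LINC03040* (16.7-fold), the cytokine receptor gene *IL21R* (15.9-fold), *PRUNE2* (14.9-fold) and the urea transporter gene *SLC14A1* (13.7-fold). *LINC03040*, a long noncoding RNA, was the most abundant of these, going from 57.8 ± 2.94 to 964 ± 201 CPM (n = 3 each). The others were scarce in DMSO, so their folds rest on low starting values. In DMSO *TTN* stood at 0.14, *PRUNE2* at 0.47, *SLC14A1* at 0.50, *PPM1K-DT* at 0.68 and *IL21R* at 0.98 CPM. Among genes of at least 5 CPM in the higher group, with a symbol and no overlap between libraries, the largest falls were the following. They were in *GPR17* (3.46-fold), *MIR17HG*, the host transcript of the miR-17 cluster (3.19-fold), *MT-ND6* (2.99-fold), *SNHG4* (2.87-fold), *ASMTL-AS1* (2.49-fold), *DNAJC2* (2.47-fold) and *ITGB1BP2* (2.40-fold). NT also differed from DMSO in the same direction at all the genes named in this paragraph except *ASMTL-AS1*. The log2 differences, NT minus DMSO, were for instance 4.47 for *SLC14A1*, 2.91 for *ACSS2*, 2.90 for *IL21R* and −2.98 for *GPR17*. They were smaller for *PPM1K-DT* (0.67) and *MT-ND6* (−0.39). The strand setting of the counting is not given in the sources used here, so values of *PPM1K-DT*, *ASMTL-AS1* and *MT-ND6* can include reads from the opposite strand.

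**Figure D2:**
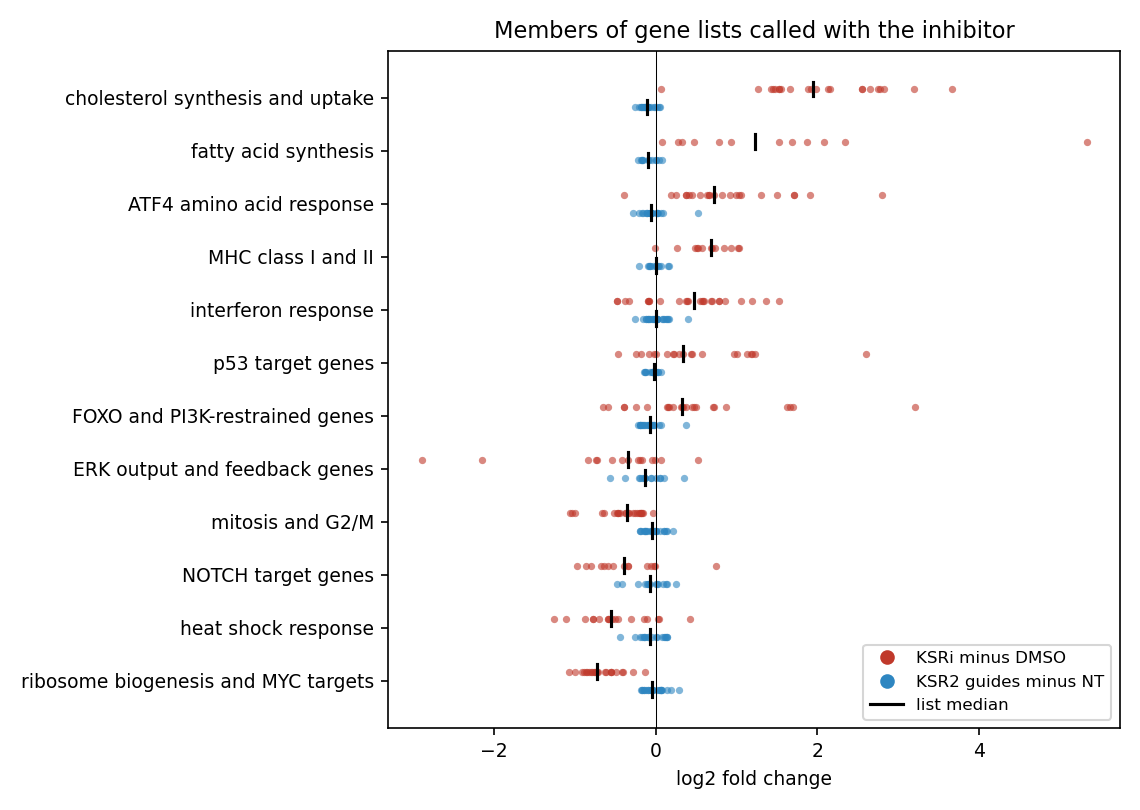
Log2 fold changes of the tested members of the 12 gene lists called with the inhibitor, for KSRi minus DMSO (red) and for the mean of both KSR2 guides minus NT (blue), with black bars for list medians. The cholesterol list had a median of 1.95 with the inhibitor and −0.11 with the guides.

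The comparisons of each guide with NT asked what the loss of *KSR2* transcript changed. Apart from *KSR2*, few genes passed the test. With guide 1, *KSR2* alone passed the test (1 gene lower and 0 higher of 18963). With guide 2, *KSR2* and *GNPNAT1*, an enzyme of UDP-N-acetylglucosamine synthesis, were lower and 0 genes were higher. Averaged over both guides 3 genes were lower and 0 higher, namely *KSR2* (45.5-fold, log2 change −5.51, SE 0.09, edgeR adjusted p = 1.65e-16), *GNPNAT1* (log2 change −0.53, SE 0.08, edgeR adjusted p = 0.0458) and ENSG00000278996. The last, named after its values were seen, rested on 1 control library, with 2.25 CPM in NT replicate 2, 0.290 CPM in NT replicate 1 and group means of 0.0345 and 0.0628 CPM with guides 1 and 2. At an unadjusted p under 0.05 there were 880 genes for guide 1, 683 for guide 2 and 788 for both, where 948 are expected by chance. Counts below the expected one may mean that these p-values were too large, which was not tested. A fit of only the groups compared called 1 gene for guide 1, 3 for guide 2 and 3 for both. DESeq2 called 9, 6 and 9 genes, edgeR without a low-count filter called 35, 35 and 41, and limma-voom called 1 for both guides. Of the 41 genes without the filter 5 were under 1 CPM. The 41 included, named after their values were seen, *RPL41P1* (log2 change 1.18, edgeR adjusted p = 1.23e-24) and *RPL41* (0.83, edgeR adjusted p = 5.33e-17), at 29.8 and 116 CPM. By its name *RPL41P1* is a pseudogene of *RPL41*, so they may share reads and may not be separate changes. Neither was called with the filter. Leaving out NT replicate 1 gave 5 genes for guide 1 and 4 for guide 2, and leaving out NT replicate 2 gave 3 for guide 1. For both guides together 1 gene was left without guide 1 replicate 1 or 3, or guide 2 replicate 1 or 2.

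Genes of the cascade and of the TAL1 circuit were examined for the mean of both guides. Of 20 cascade genes 0 passed for both guides by edgeR (1 adjusted over the list alone), with log2 changes from −0.23 to 0.15. Those with the lowest p were *MAP2K2* (−0.23, SE 0.06), *NRAS* (0.15, SE 0.07), *GRB2* (−0.16, SE 0.08) and *ARAF* (−0.13, SE 0.11). DESeq2 called *MAP2K2* with guide 1 (log2 change −0.31, DESeq2 adjusted p = 0.0239), and edgeR did not (adjusted p = 0.687). Of 15 ERK output genes 0 passed, and *SPRY2* (−0.20, SE 0.08), *SPRED2* (−0.13, SE 0.07), *SPRY1* (−0.15, SE 0.10) and *SPRY4* (−0.20, SE 0.14) had the lowest p. In the TAL1 circuit 0 of 16 passed, with *GATA3* at −0.23 (SE 0.11), *TRIB2* at −0.13 (SE 0.06) and *TCF3* at −0.11 (SE 0.07). The 10 tested neighbours of *KSR2* on 12q24 had a median of 0.01 and 0 calls. As groups, 8 of 31 lists were lower by camera with a preset correlation, but 0 were called with an estimated correlation (lowest adjusted p = 0.401) or with fry (lowest adjusted p = 0.209). These were glycolysis and hypoxia response (median −0.14, adjusted p = 7.94e-06), immediate early genes (−0.18, 6.79e-05), cholesterol synthesis (−0.11, 0.000414), LXR targets (−0.13, 0.00103), FOXO genes (−0.07, 0.00222), adhesion and cytoskeleton (−0.09, 0.0284), the TAL1 circuit (−0.08, 0.0306) and fatty acid synthesis (−0.09, 0.0306). In these 8 lists 0 members passed over all genes by edgeR with its low-count filter, and adjusted over the list alone 5 passed for glycolysis, 1 for immediate early genes and 1 for LXR targets. Without the filter edgeR called the glycolysis genes *ENO1* (adjusted p = 0.0129) and *ALDOC* (adjusted p = 0.00667), named after their values were seen. Without NT replicate 1 camera called 4 lists.

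The guides were then compared with each other. *GNPNAT1* (ENSG00000100522; chromosome 14, 52775194 to 52791668) was 2.18-fold lower with guide 2 than with guide 1 (log2 difference −1.12, SE 0.09, edgeR adjusted p = 6.40e-06). It stood at 51.0 ± 0.317 CPM with NT (n = 2), 52.3 ± 3.26 CPM with guide 1 and 24 ± 2.31 CPM with guide 2 (n = 3 each). It was the 1 gene that differed between the guides by edgeR with its low-count filter. At an unadjusted p under 0.05 there were 614 genes, where 948 are expected by chance. Without the filter edgeR called 13 genes (3 higher and 10 lower with guide 2), DESeq2 called 2, and leaving out guide 2 replicate 3 gave 2. *KSR2* differed by 0.49 (SE 0.18, edgeR adjusted p = 1) on the log2 scale and *KSR1* by −0.03 (SE 0.08). Camera placed 6 lists higher with guide 2, with medians from 0.05 to 0.08, and 0 lists with an estimated correlation (lowest adjusted p = 0.247) or with fry. Without guide 1 replicate 2, guide 1 replicate 3 or guide 2 replicate 3 it placed 3.

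Both guides shared 1 called gene, their target *KSR2*, and no other. Independent lists would share 0.000105 genes, and simulated unchanged groups with the same controls shared 0.05 on average. Since both guides were aimed at *KSR2*, this overlap says nothing about shared effects on other genes. Without a low-count filter the guides shared 13 genes (7 higher and 6 lower), with DESeq2 they shared 3, and leaving out NT replicate 1 or 2 gave 3 or 2. The log2 changes of the guides were correlated at r = 0.696 across genes, which are not independent replicates. Simulated unchanged groups that shared the NT libraries gave 0.642 (0.618 to 0.655 over 20 simulations). The covariance was 0.0474 across all genes, *KSR2* included, and 0.0414 (0.0397 to 0.0442) in the simulated groups. For genes of at least 1 CPM without *KSR2*, r was 0.658 against a simulated 0.616 (0.605 to 0.630), and the covariance was 0.0121 against 0.0125 (0.0121 to 0.0129). The simulation drew each gene independently, so its ranges may be too narrow for genes that vary together. The NT group was too small to split, so part of any excess may come from the shared controls, and it was not traced to the guides.

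Whether the inhibitor and the guides had different effects was tested directly. For cholesterol synthesis and uptake, 21 of 22 genes had a higher log2 change with the inhibitor than with the guides and 0 a lower one, and the median difference in log2 change was 2.10 (camera adjusted p = 8.72e-28, and adjusted p = 0.0168 with an estimated correlation). Ribosome biogenesis genes differed in the other direction, with 19 of 24 lower, or 22 adjusted over the list alone (median −0.68, camera adjusted p = 1.17e-12, and adjusted p = 0.00444 with an estimated correlation). So did ERK output genes, with 4 of 15 lower (median −0.27, camera adjusted p = 0.0228, but adjusted p = 0.0947 with an estimated correlation). *KSR1* differed by 0.64 (SE 0.12, edgeR adjusted p = 0.000727). In all, the effects differed at 5431 of 18963 genes by edgeR, with 3139 higher and 2292 lower for the inhibitor. Without NT replicate 1 this count was 3366. Of the 1475 genes changed at least 2-fold by the inhibitor, 1437 (97.4%) had a 95% interval of the guide effect that excluded the inhibitor effect, and 1058 (71.7%) changed by under 0.25 on the log2 scale with the guides. Each treatment was compared with its own control group, and the inhibitor and the guides share no control library. These control groups, DMSO and NT, themselves differed at 12477 of 18963 genes by edgeR. The test therefore cannot separate different effects of inhibitor and guides from different starting states of the cells.

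The inhibitor and the mean of both guides were then compared for shared calls. *GNPNAT1* was lower in both comparisons (log2 change −0.42, SE 0.08, edgeR adjusted p = 0.000696 with the inhibitor), and 0 genes were higher in both. The call with the guides was that of their average and came from guide 2 (log2 change −1.09, SE 0.09, edgeR adjusted p = 2.09e-05), since with guide 1 the log2 change was 0.04 (SE 0.09, edgeR adjusted p = 0.98). Independent lists would share 0.56 lower genes (Fisher's exact test, two-sided, p = 0.462, a description since genes are not independent). The count was 12 without a low-count filter (6 higher and 6 lower), 4 with DESeq2 and 0 with limma-voom, 3 without KSRi replicate 1, and 0 without any 1 of the DMSO or guide 1 libraries, NT replicate 2 or guide 2 replicates 1 or 2. Without NT replicate 1 it was also 1, but that gene was higher in both comparisons and *GNPNAT1* was not shared. Across genes the log2 changes of inhibitor and guides had a Pearson r of −0.077 and a Spearman rho of −0.136, against −0.016 to 0.017 for r in simulated unchanged groups. The simulation drew each gene independently and left the inhibitor without effect, so its range cannot decide whether the effects were opposed. Without NT replicate 1 r was −0.003, and without NT replicate 2 it was −0.113.

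**Figure D3:**
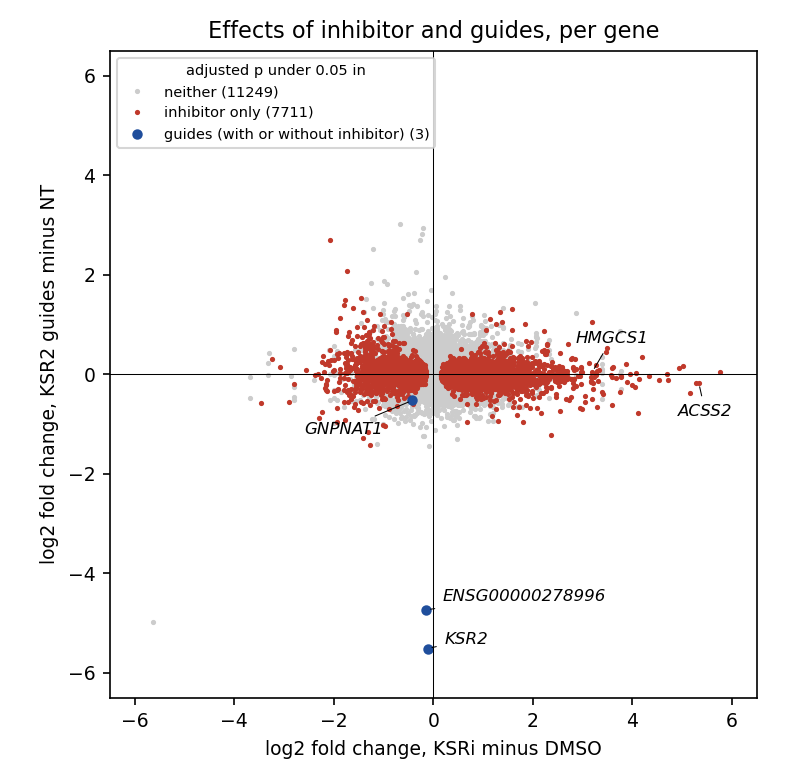
Log2 fold change with the KSR2 guides (vertical axis, mean of both guides minus NT) against log2 fold change with the inhibitor (horizontal axis, KSRi minus DMSO) for each of 18963 tested genes, coloured by the comparison in which the edgeR adjusted p was under 0.05. The genes called with the inhibitor spread along the horizontal axis, and *KSR2*, *GNPNAT1* and ENSG00000278996 are the 3 called with the guides.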

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

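The test of *GNPNAT1* between the guides was planned, and the tests of explanations for it were chosen after the result was seen. *GNPNAT1* stood out because the effects of the guides differed from each other (log2 difference −1.12, edgeR adjusted p = 6.40e-06). All 3 guide 2 libraries held less *GNPNAT1* than every NT and guide 1 library (22.4, 22.9 and 26.6 CPM, against 48.7 to 55.0 CPM). No overlap with the guide 1 libraries was a condition for naming the gene, so that part is no test. The separation from the NT libraries was not a condition of that rule and argues against 1 aberrant guide 2 library. The 9 tested genes within 500 kb had a median log2 difference of −0.003 (range −0.09 to 0.20), which argues against loss or silencing of a wider region. Of the 10 splits of the 6 guide libraries 1, the real one, gave as many genes (1 gene, against a highest of 0 in the other splits), too few splits for a share under 0.05. A candidate explanation that stays open is an unintended target of guide 2, and since guide sequences are not given in the sources used here it was not tested, nor was any biological explanation.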

How the results depend on the processing

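Alternatives chosen after the data were seen are those for NT against DMSO. *KSR2* fell with each guide and was not called with the inhibitor under every alternative run. The count for KSRi against DMSO stayed within 1.5 times of 7712 except at 2-fold or more (1475, by construction), and 0 of its genes were called with the opposite sign. The count was 6137 when only these groups were fitted and 8928 without KSRi replicate 1. Without a low-count filter the counts were 35 for guide 1, 35 for guide 2, 41 for both guides, 13 for guide 2 against guide 1, 13 shared by the guides and 12 shared by inhibitor and guides. With DESeq2 they were 9, 6, 9, 2, 3 and 4. Limma-voom called 1 gene for both guides and 0 shared with the inhibitor. Upper-quartile factors and the filter of 5 CPM each gave 2 shared with the inhibitor. At an adjusted p under 0.01 both guides had 1 gene, inhibitor and guides shared 0, and their effects differed at 2908 genes. At 2-fold or more the last was 1413, with 0 shared. With each library left out the count ranged from 1 to 5 for guide 1, 2 to 4 for guide 2, 1 to 3 for both guides, 1 to 2 between guides, 1 to 3 shared by the guides, 0 to 3 shared with the inhibitor and 3366 to 7377 for the difference of effects. The correlation of inhibitor and guide effects was −0.019 without a filter, −0.159 with the filter of 5 CPM, −0.143 when only the groups compared were fitted, −0.193 above the median abundance and −0.113 to −0.003 with a library left out. Gene lists called numbered 6 for the inhibitor and 4 for the difference of effects with an estimated correlation, and 0 for guide 1, guide 2, both guides and guide 2 against guide 1. Fry called 20 for the inhibitor, 21 for the difference of effects and 0 for the 4 comparisons among guides and NT. With a library left out, lists ranged from 5 to 11 for guide 1, 3 to 10 for guide 2, 4 to 10 for both guides and 3 to 9 between guides. The causes were not tested, except that thresholds lower counts by construction. For single genes and lists 2162 of 2209 alternatives kept direction and call, 46 lost the call and 1 turned direction (*KSR1* in guide 2 against guide 1, −0.05 to 0 with a library left out and 0 without guide 2 replicate 2, not called in any). The replicate numbers are shared between groups, but same-numbered libraries did not deviate together (correlations −0.10 to 0.11), so they do not pair the samples. Of the 6 DMSO and KSRi libraries 1 correlated best with its own number, and of the 6 guide libraries 0. With a block for the number, KSRi against DMSO had 7409 genes, guide 1 had 2, guide 2 had 2, both guides had 2 and inhibitor and guides shared 0. NT against DMSO had 5292 genes at 2-fold or more and 8341 to 12973 under the other alternatives. Depth was not varied on its own. Of simulated 1.5-fold changes in genes of at least 1 CPM, 74.6% were recovered for both guides.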

Other observations

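In this part the tests of explanations and the comparison of NT with DMSO were chosen after results were seen, while the gene lists and splits were planned. Several further lists of genes moved with the inhibitor in part. Of 27 tested genes of T-cell receptor and proximal signalling 11 rose and 1 fell (median log2 change 0.17, camera adjusted p = 0.167), among them the costimulatory receptor gene *CD28* (1.52-fold). Glycolysis and hypoxia genes split, with 10 of 25 higher and 8 lower (median −0.09, mean 0.23, higher by camera at adjusted p = 0.836). *ALDOC* rose 8.22-fold, *VEGFA* 3.87-fold and *PFKFB4* 2.78-fold, while *LDHA* fell 1.64-fold. ER chaperone genes split as well, with 5 of 21 higher and 6 lower (camera adjusted p = 0.736). *DNAJB9* rose 1.94-fold, while the chaperones *HSP90B1* and *HSPA5* fell 1.85-fold and 1.57-fold. In the DNA replication list 9 of 25 fell and 2 rose (camera adjusted p = 0.0571), and 12 passed adjusted over the list alone. *BMF*, a death-promoting member of the BCL2 family, rose 2.82-fold and *BBC3* 2.35-fold, and of that family 5 of 15 rose and 2 fell (camera adjusted p = 0.154). Among immediate early genes *ATF3* rose 2.85-fold, *JUND* 1.95-fold and *JUN* 1.74-fold, with 6 of 19 higher and 3 lower (camera adjusted p = 0.405). The 19 lists not called had camera adjusted p from 0.0571 to 0.956. Except for DNA replication, the counts adjusted over the list alone equalled those over all genes in the lists of this paragraph.

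With the guides, DESeq2 called genes that edgeR with its low-count filter did not. For both guides these included *CCDC28A* (log2 change 0.51), *ESD* (0.66), *AK4*, a mitochondrial adenylate kinase (−0.38), *ID1* (−0.62) and *HSPA6* (−0.82), named after their values were seen. Their edgeR adjusted p values were 0.0983, 0.947, 0.889, 0.643 and 0.643, and without the filter edgeR called all but *AK4*. For markers of other cell types, the summed level of 12 myeloid markers was 1.06 CPM in DMSO and 0.819 CPM in NT, and 1 of them was tested. B-cell markers summed to 93.8 CPM in DMSO and 99.5 CPM in NT, of which *IGLL1* held 69.1 and 36.6 CPM. The other B-cell markers together were therefore higher in NT than in DMSO. Erythroid and megakaryocyte markers summed to 821 CPM in DMSO and 311 CPM in NT, of which the transferrin receptor gene *TFRC*, used by dividing cells, held 813 and 290 CPM.

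The inhibitor changed 7712 genes and the mean of both guides 3. For the genes changed 2-fold by the inhibitor, too little power in the CRISPR libraries is argued against. For 97.4% of them the 95% interval of the guide effect excluded the inhibitor change (91.7% to 97.6% with a library left out). These are 1475 of the 7712 genes, and the smaller changes of the others were not covered. Also argued against are *KSR2* transcript left in the guide libraries (2.21% of NT) and a rise of *KSR1* there over NT (upper 95% limit of the log2 change 0.092). Whether the CRISPR cells were already in the state the inhibitor produces cannot be decided for the contrast as a whole. For cholesterol genes, which rose with the inhibitor, it is argued against. Of these, 17 of 22 were lower in NT than in DMSO and 1 was higher (median log2 difference −0.75). Ribosome biogenesis genes were lower in NT in 24 of 24 cases, as with the inhibitor, so for them it stays open. Of the genes changed 2-fold by the inhibitor, 51.4% differed between NT and DMSO the same way by at least as much (49.2% to 53% with a library left out). Of the rest, 95.7% had an interval that excluded the inhibitor change (86.3% to 96.2%). The 51.4% rests on comparisons that share the DMSO libraries, and its value in unchanged groups was not simulated. Of the 10 splits of the KSRi and DMSO libraries 1, the real one, gave as many genes (7712, against a highest of 0 in the other splits), too few splits for a share under 0.05. Targets of the inhibitor beside KSR2, KSR1 among them, and KSR2 protein may each account for the contrast, and neither was tested.

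DMSO and NT libraries, the control groups, differed at 12477 of 18963 genes (6568 higher and 5909 lower in NT). Upper-quartile factors moved the median of all genes from 0.04 to 0.26 and the split to 8283 higher and 4187 lower. Heat shock genes were lower in NT in 17 of 18 cases (median log2 difference −2.03, camera adjusted p = 1.35e-09, and adjusted p = 0.00204 with an estimated correlation), and ribosome biogenesis genes in 24 of 24 (median −1.64, camera adjusted p = 1.03e-13, and adjusted p = 0.00204 with an estimated correlation). Cholesterol genes were lower in NT in 17 of 22 cases and higher in 1 (median −0.75, camera adjusted p = 2.47e-05, but adjusted p = 0.3 with an estimated correlation), opposite to their rise with the inhibitor. ER chaperone genes were higher in 20 of 21 (median 1.27, camera adjusted p = 4.10e-08, but adjusted p = 0.225 with an estimated correlation). As with the inhibitor, ATF4 response genes were higher in 19 of 23 cases and lower in 0 (median 1.33, camera adjusted p = 2.45e-07, but 0.292 with an estimated correlation). MHC genes were higher in 10 of 13 and lower in 3 (median 1.46, camera adjusted p = 0.0192, but 0.451 with an estimated correlation). Camera called 13 of the 31 lists in all, and 2 with an estimated correlation. Adjusted over the list alone the counts of the lists named here were the same.

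Of 5820 genes called both in NT and in KSRi against DMSO, 5053 (86.8%) went the same way, where independent lists would share 1450 higher and 1100 lower genes and 2695 and 2358 were seen. Chance values from the shared DMSO libraries are argued against as the whole cause, since the covariance of the log2 changes was 0.294 against at most 0.0110 in simulated unchanged groups. Different cell lines are argued against, since the number of T-cell receptor beta variable genes that led a library was 1, *TRBV12-3* in every library. Its share of such counts nevertheless differed between the sets, at 89.0% to 90.7% in DMSO and KSRi libraries and 71.5% to 78.4% in NT and guide libraries, and whether another clone of the line or other cells were present was not tested. Batch, culture or transduction cannot be told apart from one another, because no library of one set shares a condition with the other, and any of them may underlie the 12477 genes. No biological explanation was tested.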
